A study of Mus musculus with 12 samples.

How the data were processed

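The samples were 12 RNA sequencing libraries of mouse bone marrow-derived macrophages in 4 groups of 3: unstimulated wild type (WT_M0), unstimulated knockout (cKO_M0), and each genotype after stimulation with lipopolysaccharide at 100 ng/ml and interferon-gamma at 10 ng/ml (WT_M1 and cKO_M1), per the labels' protocols. Culture in L929-conditioned medium lasted 7 days. Groups were taken from the sample labels, and every library was used.

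The deposited values were raw counts per gene, with 1 column per library and a gene length, and no normalization. Per the submitters' processing notes, reads were processed with Trimmomatic 0.39, HISAT2 2.2.1, SAMtools 1.16.1 and featureCounts 2.0.3 on the genome build GRCm39; the strand option, the treatment of reads that match several places and the annotation release are not given in the sources used here. The Length column (in bases, per the file headers) was not used in any test. The table held 56980 gene IDs, of which 52073 matched a symbol in a reference name table; the 4907 others held 0.156% to 0.243% of the counts of a library and stayed in the tests. The reference table of neighbouring genes was of another mouse assembly, GRCm38, and was used only for names and gene order. Library totals lay between 41721452 and 42197986 counts. Of the values from 1 to 10 in the table, 60.9% were even, where about 50% would be usual (13477 values of 1 against 20717 of 2). Read pairs counted by mate would leave such an excess, but this was not stated, so counts were used as deposited and, as an alternative chosen after seeing the data, halved.

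Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the 4 groups (minimum count 10, minimum total count 15), which left 15110. Libraries were scaled by TMM factors, which averaged 1.21 in WT_M0, 1.22 in cKO_M0, 0.808 in WT_M1 and 0.840 in cKO_M1. A model with 1 mean per group was fitted to all 12 libraries, so that the groups shared 1 estimate of the spread (common biological coefficient of variation 0.111). Contrasts were tested with edgeR's quasi-likelihood F-test and Benjamini-Hochberg adjustment over all tested genes. A gene passed at an adjusted p under 0.05. The contrasts were cKO against WT in M0 and in M1, M1 against M0 in WT and in cKO, the difference between the cKO effects in M1 and M0 (interaction), and their mean over both states. Log2 fold changes are those of edgeR, with a standard error taken from the fold change and the F statistic; levels are CPM, which are counts scaled to a common library size, on the TMM scale with the SD over the libraries of a group. Intervals are 95% intervals. A fold against a group with no counts was given only as a lower bound, with 3 counts per library as the floor.

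In total 30 gene lists with 764 entries were fixed before the data were examined, 1 entry of which had no match: type I interferon-stimulated genes, interferon-gamma response genes, proinflammatory mediators, chemokines, alternative (M2) macrophage genes, MHC class II and class I antigen presentation, NF-kB pathway, Regnase family and mRNA decay, reported Regnase-1 targets and splicing factors. Further lists were those of RANK signalling and osteoclast genes, cell cycle, cholesterol synthesis, glycolysis and hypoxia, unfolded protein and integrated stress response, NRF2, lysosome and phagocytosis, macrophage identity, extracellular matrix and immediate early genes. The marker lists were those of neutrophils, T and NK cells, B and plasma cells, erythroid cells, mast cells, basophils and eosinophils, dendritic cells, megakaryocytes and platelets and stromal cells, and sex-linked genes. The lists were written from general knowledge, and members with other symbols were matched through synonyms. Several lists share members, so their results are not separate. Lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast, and again with an estimated correlation and with fry; the 29 lists with at least 3 tested members were tested. Members were also adjusted over the list alone. A list's median, mean and test differed in sign for 7 lists in M0, 5 in M1, 2 and 4 for M1 against M0 in WT and cKO, 3 in the interaction and 5 over both states, and 0 of these lists passed.

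The genes named were set by a rule written at the same time: the Zc3h12 family and Tnfrsf11a. For each comparison of 2 groups, it took the 10 genes with the largest change each way among those that passed, with at least 5 CPM in the higher group and no overlap between the libraries of the groups (chance gives no overlap for 10% of genes with 3 against 3), skipping predicted genes. It took for each list up to 4 members with the smallest p that passed, or 2 where none did. It added, for the interaction, the 10 genes with the smallest p at the same level. The same was done for the mean over both states, for which the rule set no number of genes. Genes outside this rule are marked as chosen after their values were seen. Overlaps of calls were compared with independent lists and, for M0 and M1, tested with Fisher's exact test. The fit and the test were tested on simulated data, in which counts were drawn at the real means and depths, independently for each gene, with 200 genes changed. With M0 simulated (14863 genes), 46 of 67 genes changed 1.5-fold (68.7%), 64 of 67 changed 2-fold (95.5%) and all 66 changed 4-fold passed, with 4 false calls. With M1 simulated (14866 genes) these were 51 of 67 (76.1%), 61 of 67 (91.0%) and 66, with 10 false calls.

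The alternatives were DESeq2 1.42.0, median-of-ratios factors, library totals alone, no low-count filter, a filter of 5 CPM in 3 libraries, a fit of the compared groups alone, a robust fit, limma-voom, an added threshold of 1 on the absolute log2 fold change, and leaving out each library in turn. Adjusted p-values that DESeq2 left empty (3225 genes in M0 and 590 in M1) stayed empty. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Splicing, exon use and reads over the deleted exons were not analysed here, since the table holds 1 total per gene.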

Results

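Gene expression was measured by RNA sequencing in mouse bone marrow-derived macrophages, which are macrophages grown in culture from bone marrow, here for 7 days in medium conditioned by the L929 cell line. The cells came from wild-type mice (WT) or from mice named as RankCre conditional knockouts of Regnase-3 (cKO). Regnase-3 is the CCCH-type zinc finger protein encoded by Zc3h12c, and RANK is the receptor encoded by Tnfrsf11a. The cultures were either left unstimulated (M0) or stimulated with lipopolysaccharide (LPS) at 100 ng/ml together with interferon-gamma at 10 ng/ml (M1). The question stated for the series was what Regnase-3 does in the polarization of Rank-positive macrophages. There were 12 libraries in 4 groups of 3, and the total per library lay between 41721452 and 42197986 counts. Along the first principal component, which held 85.1% of the variance, the M0 libraries separated from the M1 libraries. WT and cKO separated within each state along the second component, which held 4.33%, with cKO_M0 replicates 1, 2 and 3 at 2.13, -11.8 and -11.9 and the WT_M0 libraries at 5.89 to 9.58. The labels call the control mice wild type and do not describe a Cre-only control, so an effect of Cre and an effect of the deletion could not be separated. They also do not state that the replicates were separate animals or cultures, so p-values measure the spread between these samples, whether technical or biological.

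The targeted gene was read first in every library. Zc3h12c (ENSMUSG00000035164) had 878, 819 and 794 counts in WT_M0 replicates 4, 5 and 6, and 703, 944 and 751 counts in cKO_M0 replicates 1, 2 and 3. In M1 it had 6020, 6392 and 5424 counts in WT replicates 10, 11 and 12, and 3463, 3652 and 4484 counts in cKO replicates 7, 8 and 9. In M0 the cKO level, 15.6 ± 2.57 CPM (counts scaled to a common library size; SD, n = 3), did not differ detectably from the WT level of 16.4 ± 0.773 CPM (log2 fold change -0.07, SE 0.12, adjusted p = 0.809, 95% interval -0.33 to 0.19). In M1 Zc3h12c fell from 176 ± 16.6 to 109.6 ± 15.2 CPM (log2 fold change -0.68, SE 0.12, adjusted p = 0.00101, 95% interval -0.93 to -0.43), to 62.4% of the WT level. The table gives totals per gene, so exons outside the deleted part still count, and which exons were deleted is not given in the sources used here. M1 stimulation itself raised Zc3h12c, with a log2 fold change of 3.42 in WT and 2.81 in cKO. Tnfrsf11a, the gene whose name the Cre carries, lay between 106 and 137 CPM in the 4 groups and was not called between WT and cKO in M0 (adjusted p = 0.789) or M1 (adjusted p = 0.935). Of the related genes, Zc3h12a, which encodes Regnase-1, had log2 fold changes of -0.02 in M0 and 0.12 in M1. Zc3h12d had 0.06 and 0.09 and Zc3h12b -0.35 and -0.37, and none of these passed the test.

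**Figure D1:**
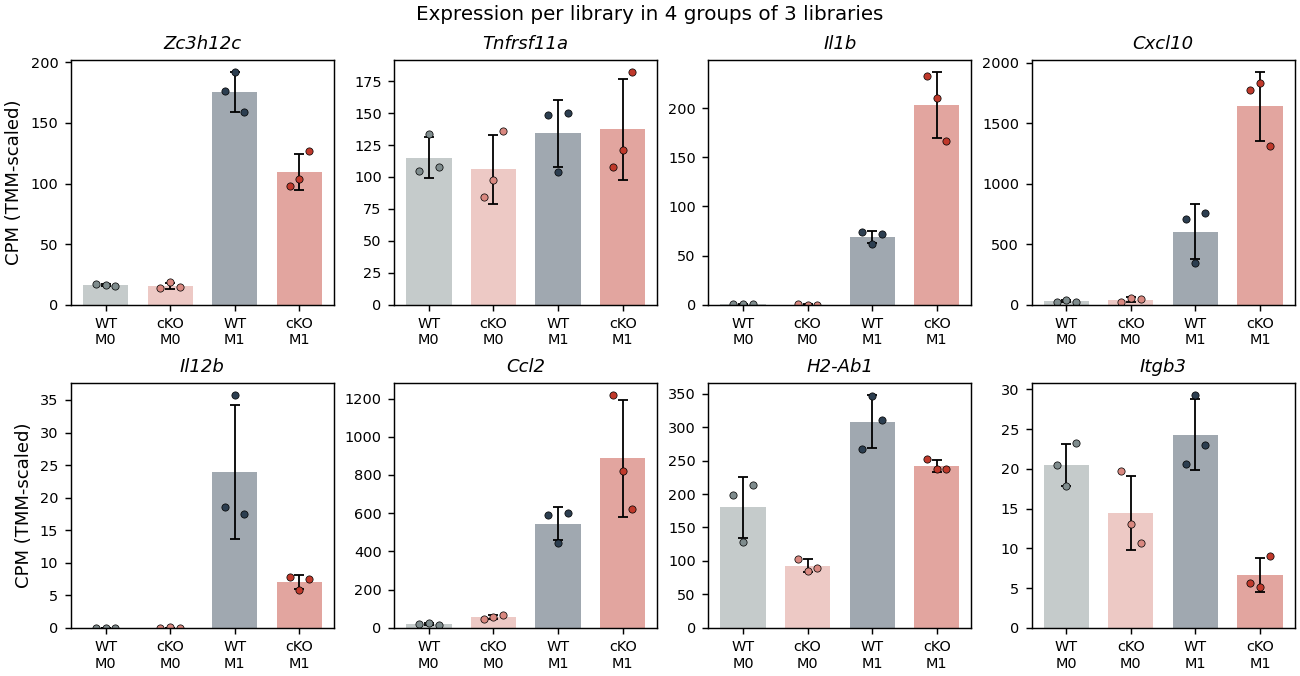
Expression of 8 genes in CPM (vertical axes, linear, from 0) in the 4 groups. Bars give the mean, error bars the SD and points the 3 libraries of each group; Zc3h12c is lower in cKO in M1, Il1b and Cxcl10 are higher and Il12b and Itgb3 lower in cKO in M1, and Ccl2 is higher and H2-Ab1 lower in cKO in M0.

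The first comparison asked what differed between cKO and WT macrophages before stimulation. In M0, Ccl2, which encodes a chemoattractant of monocytes, rose in cKO from 19.4 ± 5.56 to 55.1 ± 10.99 CPM (SD, n = 3; log2 fold change 1.51, SE 0.24, adjusted p = 0.0105), and Ccl7 and Cxcl2 rose by log2 fold changes of 1.56 (SE 0.28) and 1.03 (SE 0.20). Ciita, the transcriptional coactivator of the class II genes, fell from 43.3 ± 8.67 to 19.9 ± 2.38 CPM (log2 fold change -1.12, SE 0.15, adjusted p = 0.00497). The class II chain gene H2-Ab1 fell from 180.3 ± 45.4 to 92.5 ± 9.77 CPM (log2 fold change -0.96, SE 0.15, adjusted p = 0.0105). The metalloproteinase gene Mmp14 fell from 11.6 ± 3.00 to 3.78 ± 1.52 CPM (log2 fold change -1.62, SE 0.23, adjusted p = 0.00980). Over all genes, 244 of 15110 tested changed, 100 higher and 144 lower in cKO, of which 14 and 19 by at least 2-fold. Without cKO_M0 replicate 3, 0 genes passed as higher and 1 as lower, and without WT_M0 replicate 6, 0 and 4. The rises of Ccl2, Ccl7 and Cxcl2 thus did not pass in either fit. At most 1 of the falls named here passed without cKO_M0 replicate 3.

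Of the genes with the largest changes in M0, Cenpk, Raet1d, Glipr2, Dusp5, Hmga2, Rgs1 and Hmgn3 also rose, by log2 fold changes of 1.09, 1.03, 0.89, 0.82, 0.81, 0.79 and 0.76 (adjusted p between 0.0103 and 0.0442). Eps8l1, Mgll (monoacylglycerol lipase), Sorbs3, Dio2 (the type 2 iodothyronine deiodinase), Gpr162, Ms4a4a and Peli2 fell, with log2 fold changes of -1.39, -1.26, -1.23, -1.23, -1.02, -0.99 and -0.95 (adjusted p between 0.0210 and 0.0449). Each of these genes had at least 5 CPM in the higher group and no overlap between the 3 cKO and the 3 WT libraries.

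Among the gene lists, the MHC class II list had 7 of 15 measured members lower and 0 higher (7 lower when adjusted over the list alone; camera adjusted p = 1.84e-12, and adjusted p = 0.0927 with an estimated correlation). H2-Aa fell by 0.93 and Cd74, the invariant chain, fell by 0.92 on the log2 scale. B cells also express class II genes. None of 4 B cell and plasma cell markers passed in M0 (camera adjusted p = 0.136, and adjusted p = 0.575 with an estimated correlation), but that list reached adjusted p = 1.47e-10, lower in cKO, without cKO_M0 replicate 1. Igkc, an immunoglobulin gene chosen after the values were seen, had 318, 4 and 0 counts in cKO_M0 replicates 1, 2 and 3 against 171 to 386 in WT_M0. In replicate 1 H2-Ab1 was at 103.5 CPM, below the 128.5 to 213 CPM of the WT_M0 libraries. Of 22 chemokine genes, 4 rose and none fell (6 when adjusted over the list alone; camera adjusted p = 1.06e-05, and adjusted p = 0.0927 with an estimated correlation), Ccl9 among them at 0.51. Cell-cycle genes rose: 4 of 42 passed over all genes and 20 when adjusted over the list alone, all of them higher (camera adjusted p = 9.09e-16, and adjusted p = 0.0998 with an estimated correlation). These included the G1/S cyclins Ccne1 and Ccne2 at 0.56 and 0.67 and Pcna at 0.51. In the RANK signalling and osteoclast list, 3 of 18 members fell and none rose (7 lower when adjusted over the list alone; camera adjusted p = 3.37e-05, and adjusted p = 0.0927 with an estimated correlation). They were the kinase gene Src at -0.66, Mmp9 at -1.07 and Acp5, tartrate-resistant acid phosphatase, at -0.75. Lysosome and phagocytosis genes fell as a list (3 lower and 1 higher of 31; 10 lower and 4 higher when adjusted over the list alone; camera adjusted p = 0.00854, and adjusted p = 0.0927 with an estimated correlation). Mertk, a receptor for the uptake of apoptotic cells, fell by 0.72 and Fcgr2b fell by 0.81, whereas Msr1 rose by 0.31 on the log2 scale.

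In M0, 6 further lists passed with the preset correlation. Unfolded protein and integrated stress response genes (1 of 25 higher, Chac1 at 0.88; 8 higher and 2 lower when adjusted over the list alone; camera adjusted p = 0.0368, and adjusted p = 0.575 with an estimated correlation) rose as a list. The call was lost without cKO_M0 replicate 2 or 3 or WT_M0 replicate 4 (adjusted p = 0.139, 0.0555 and 0.0833). Glycolysis and hypoxia genes rose as a list with none of 27 members past the test over all genes and 5 when adjusted over the list alone (camera adjusted p = 0.00465, and adjusted p = 0.575 with an estimated correlation). It was lost without cKO_M0 replicate 2 or WT_M0 replicate 4 (adjusted p = 0.0556 and 0.0853). Splicing factor genes also rose as a list, with 1 of 81 members past the test, U2af1 at 0.41 (camera adjusted p = 0.0368, and adjusted p = 0.638 with an estimated correlation). This was lost without cKO_M0 replicate 2 or WT_M0 replicate 4 or 6 (adjusted p = 0.274, 0.291 and 0.0554). None of 35 type I interferon-stimulated genes passed over all genes or when adjusted over the list alone, Ifitm3 having a value of 0.27 and Oas1a of 0.31. The list as a whole rose (camera adjusted p = 0.0148, and adjusted p = 0.690 with an estimated correlation), and that call was lost without cKO_M0 replicate 2 or 3 or WT_M0 replicate 6 (adjusted p = 0.914, 0.237 and 0.230). Its lowest camera adjusted p without 1 library was 2.10e-17. The list did not pass with all libraries in the interaction (0.0980) or over both states (0.249). Without cKO_M0 replicate 1 it passed as lower in the interaction (1.89e-09) and as higher over both states (1.79e-05). The same held without WT_M0 replicate 5 (0.00665 and 0.0410). NF-kB pathway genes fell as a list, with the ubiquitin ligase gene Birc3 lower at -0.39 and Tnip3 higher at 0.50 (camera adjusted p = 0.00952, and adjusted p = 0.575 with an estimated correlation). That call was lost without cKO_M0 replicate 1 (adjusted p = 0.270). Megakaryocyte and platelet markers fell as a list, with Vwf at -0.69 the member that passed of 9 (camera adjusted p = 0.0451, and adjusted p = 0.575 with an estimated correlation). Their call was lost without cKO_M0 replicate 2 or 3 or WT_M0 replicate 6 (adjusted p = 0.180, 0.155 and 0.137). The call of the lysosome and phagocytosis list was lost without cKO_M0 replicate 2 (adjusted p = 0.0556).

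The other lists did not pass in M0 with all libraries. Of the interferon-gamma response genes, 1 was higher, Ly6a at 1.08, and 3 were lower, Ciita, Il18bp at -0.48 and Cd274, which encodes PD-L1, at -0.44 (camera adjusted p = 0.867, turning to 0.00780 with the list higher without cKO_M0 replicate 1). Among 28 proinflammatory mediators, Ptgs2 rose by 1.19 from 0.632 ± 0.179 CPM and Tnf rose by 0.52 from 24.8 ± 1.52 CPM (camera adjusted p = 0.136, and 0.0240, 0.0450 and 0.0328 without cKO_M0 replicate 1 or 3 or WT_M0 replicate 4). The reported Regnase-1 target mRNAs had Id1, Ptgs2 and Cxcl2 higher of 26 (Id1 at 1.82; camera adjusted p = 0.500). The MHC class I list, at adjusted p = 0.786, passed as higher without cKO_M0 replicate 1 (0.0143). Passing as lower were neutrophil markers (0.152 with all libraries) without cKO_M0 replicate 1 (0.0249) or WT_M0 replicate 5 (0.00507) and mast cell, basophil and eosinophil markers (0.500) without cKO_M0 replicate 1 (0.0363). So did macrophage identity genes (0.116) without WT_M0 replicate 5 (0.00731) and the Regnase family and mRNA-decay list (0.239) without cKO_M0 replicate 2 (0.0457). Spp1, which encodes osteopontin, rose by 0.52, Cx3cr1 rose by 0.65 and Folr2 rose by 0.61, whereas Csf3r, Cd4 and Itgax fell, with log2 fold changes of -0.76, -0.81 and -0.64. Leaving out 1 library moved the count of 244 changed genes to 32 without cKO_M0 replicate 2, 1 without cKO_M0 replicate 3, 12 without WT_M0 replicate 4, 407 without WT_M0 replicate 5 and 4 without WT_M0 replicate 6. The count was 394 in a fit of the 6 M0 libraries alone, 491 with limma-voom, 874 with DESeq2 and 1182 with no low-count filter, where 709 genes (60.0%) were higher in cKO, against 41.0% in the main test and 49.3% with library totals alone.

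The second comparison asked how cKO and WT macrophages differed after LPS and interferon-gamma. In M1, Il1b, which encodes the cytokine IL-1 beta, rose in cKO from 69.1 ± 6.36 to 204 ± 33.8 CPM (SD, n = 3; log2 fold change 1.56, SE 0.15, adjusted p = 3.48e-05). The chemokine gene Cxcl10 rose from 602 ± 226 to 1640.1 ± 285 CPM (log2 fold change 1.45, SE 0.33, adjusted p = 0.00702). Il12b, which encodes the p40 subunit of IL-12 and IL-23, fell from 23.97 ± 10.3 to 7.03 ± 1.04 CPM (log2 fold change -1.77, SE 0.25, adjusted p = 0.000425). The integrin beta 3 gene Itgb3 fell from 24.3 ± 4.50 to 6.59 ± 2.13 CPM (log2 fold change -1.88, SE 0.24, adjusted p = 0.000106). Ppp1r15a, a gene of the integrated stress response, also fell (log2 fold change -1.05, SE 0.13, adjusted p = 0.000106). Over all genes, 2818 of 15110 changed, 1357 higher and 1461 lower in cKO, of which 170 and 350 by at least 2-fold.

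The largest rises in M1 were those of Txnip, thioredoxin-interacting protein, from 13.3 ± 4.48 to 58.9 ± 15.9 CPM (log2 fold change 2.14, SE 0.22, adjusted p = 3.66e-05), of the ERK phosphatase gene Dusp6 at 1.78 and of the transcription factor gene Klf2 at 1.68. Fam43a, Plxdc2, Ch25h (cholesterol 25-hydroxylase), Fam72a and Gpr18 rose by 1.65, 1.56, 1.53, 1.48 and 1.45 on the log2 scale. The largest falls were those of Cdkn1c, which encodes the cyclin-dependent kinase inhibitor p57, from 29.1 ± 8.71 to 4.26 ± 1.28 CPM (log2 fold change -2.77, SE 0.27, adjusted p = 3.48e-05), Gdf3 at -2.75, Cited4 at -2.60, Klf9 at -2.27 and Mreg at -2.19. Sorbs3, Dio2, Mgll and Gprc5b fell, with log2 fold changes of -2.08, -2.08, -2.03 and -1.90. These rankings took genes at or above 5 CPM in the higher group, with no overlap between the libraries of the 2 genotypes, and their adjusted p-values lay between 2.19e-05 and 0.00702.

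In M1, of 28 proinflammatory cytokines and mediators, 11 rose and 3 fell (12 and 3 when adjusted over the list alone; camera adjusted p = 0.00118, and adjusted p = 0.234 with an estimated correlation). Beside Il1b, the scavenger receptor gene Marco rose by 1.21 (SE 0.15), whereas Il12b and Tnfsf15, at -1.49, fell. The list of NF-kB pathway and feedback regulators had 14 of 27 members higher and 2 lower (14 and 4 when adjusted over the list alone; camera adjusted p = 0.000142, and adjusted p = 0.234 with an estimated correlation). The members with the smallest p included Nfkbie, which encodes the inhibitor IkB-epsilon, at 0.80, Nfkbiz, which encodes the nuclear protein IkB-zeta, at 1.04, and Irak3, which limits Toll-like receptor signalling, at 0.64. Nfkb1 rose by 0.53. Among reported Regnase-1 target mRNAs, 11 of 26 rose and 2, Il12b and Zc3h12c, fell (11 and 3 when adjusted over the list alone; camera adjusted p = 0.000914, and adjusted p = 0.0823 with an estimated correlation). That list holds the targeted gene itself. It shares members with the proinflammatory, chemokine, NF-kB and immediate early lists, such as Il1b, Cxcl1, Nfkbiz and Egr1. Immediate early genes rose, 9 of 22 against 2 lower (11 and 3 when adjusted over the list alone; camera adjusted p = 8.92e-05, and adjusted p = 0.202 with an estimated correlation). Examples were Ier2 at 1.29, Btg2 at 1.17 and Egr1 at 1.12. Interferon-gamma response genes rose, 7 against 1 lower of 30 (9 and 1 when adjusted over the list alone; camera adjusted p = 0.00309, and adjusted p = 0.526 with an estimated correlation). Examples were Socs1, an inhibitor of interferon signalling, at 1.24, Upp1 at 0.90 and Ido1 at 0.83. The type I interferon-stimulated genes did not move as a list: 1 of 35 passed over all genes, Oas2 at -0.48, and none when adjusted over the list alone (camera adjusted p = 0.818). The Oas2 call was lost without cKO_M1 replicate 7 or WT_M1 replicate 11 (adjusted p up to 0.0570). Chemokine genes went both ways, 7 higher and 3 lower of 22 (9 and 3 when adjusted over the list alone; camera adjusted p = 0.311, and 0.0346 as higher without cKO_M1 replicate 9). Examples were Cxcl1 higher at 1.25, Cxcl2 higher at 0.79 and Ccl9 lower at -0.52.

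In the RANK signalling and osteoclast list in M1, 10 of 18 members fell and 1 rose (11 and 2 when adjusted over the list alone; camera adjusted p = 1.33e-05, and adjusted p = 0.0823 with an estimated correlation). The proton pump subunit genes Atp6v0d2 and Atp6v1c1 fell, with log2 fold changes of -1.83 (SE 0.25) and -0.67 (SE 0.09), as did Src at -0.65. Lysosome and phagocytosis genes fell, 11 of 31 against 1 higher, Marco (14 and 1 when adjusted over the list alone; camera adjusted p = 0.000988, and adjusted p = 0.0823 with an estimated correlation). Axl, a receptor for the uptake of apoptotic cells, fell from 291 ± 20.4 to 132 ± 16.7 CPM (log2 fold change -1.14, SE 0.10, adjusted p = 3.14e-05). Gpnmb fell from 10023 ± 252 to 5410 ± 1021 CPM, and Lipa, lysosomal acid lipase, fell by 0.57 on the log2 scale. Of 25 unfolded protein and integrated stress response genes, 13 fell and none rose over all genes (16 lower and 2 higher when adjusted over the list alone; camera adjusted p = 8.58e-07, and adjusted p = 0.112 with an estimated correlation), including Asns, asparagine synthetase, at -0.98, Phgdh at -1.29 and Herpud1 at -0.69. Extracellular matrix and profibrotic genes had 8 of 25 members lower and none higher over all genes (8 lower and 1 higher when adjusted over the list alone; camera adjusted p = 0.00208, and adjusted p = 0.112 with an estimated correlation). Examples were Spp1 lower at -0.85, Pdgfa at -1.52, the urokinase gene Plau at -1.28 and Timp2 at -0.64. The MHC class II list fell (4 lower and 1 higher of 15; 6 and 1 when adjusted over the list alone; camera adjusted p = 0.0411, and adjusted p = 0.454 with an estimated correlation). Of the 6 fits without 1 library, this call was kept without cKO_M1 replicate 7 and otherwise lost, with adjusted p = 0.0536 to 0.0911 without cKO_M1 replicate 8 or 9 or WT_M1 replicate 10, 11 or 12, and it was also lost with library totals alone (adjusted p = 0.0530). Its members with the smallest p were Ifi30 at -0.45 and Ciita at -0.63. Of the B cell and plasma cell markers, 1 of 4 measured passed over all genes, Ighm, which fell from 2.11 ± 0.752 to 0.227 ± 0.170 CPM (log2 fold change -3.20, SE 0.45, adjusted p = 0.000223; 2 lower when adjusted over the list alone; camera adjusted p = 0.00511, and adjusted p = 0.202 with an estimated correlation). The immunoglobulin light chain gene Igkc, chosen after the values were seen, had 31 to 386 counts in the 6 WT libraries and cKO_M0 replicate 1 and 0 to 4 in the other 5 cKO libraries.

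Glycolysis and hypoxia genes rose in M1 cKO, 10 of 27 against 2 lower (10 and 2 when adjusted over the list alone; camera adjusted p = 0.00755, and adjusted p = 0.498 with an estimated correlation). Pdk1, which inhibits pyruvate dehydrogenase, rose by 0.71, Egln1 rose by 0.63 and the hexokinase gene Hk1 rose by 0.52, while Vegfa fell, at -1.17. Members of other lists changed without the list passing. Among 81 splicing factor and spliceosome genes, 13 rose and 7 fell (15 and 10 when adjusted over the list alone; camera adjusted p = 0.251). Examples were the kinase gene Clk4 at -1.06, Srsf2 at -0.76, Srsf9 at 0.56 and Srsf1 at 0.43. Totals per gene hold no splice forms, so splicing itself was not analysed here. Of the Regnase family and mRNA-decay regulators, 4 rose and 4 fell of 24 (camera adjusted p = 0.982); Zfp36l2, Ago2 and Malt1 fell, with -1.25, -0.81 and -0.72. Cell-cycle genes had 2 higher and 6 lower members of 42 (camera adjusted p = 0.452), Mki67 at -1.04 and Kif23 at -0.90. Alternative (M2) macrophage genes had 3 higher and 8 lower of 28 (camera adjusted p = 0.105). Examples were the mannose receptor gene Mrc1 at -1.03, Gas6 at -0.85 and Il1rn, the IL-1 receptor antagonist, at -0.59. Cholesterol synthesis genes had 3 lower and none higher of 24 (camera adjusted p = 0.121; Insig1 at -0.91). NRF2 and oxidative stress genes had 2 higher and 5 lower of 19 (camera adjusted p = 0.359; Abcc1 at 0.79). Macrophage identity genes had 5 higher and 2 lower of 25 (camera adjusted p = 0.363; Cd14 at 0.79 and Cd68 at -0.46). No MHC class I gene of 23 passed (camera adjusted p = 0.731), Erap1 having a value of -0.22 and Pdia3 of 0.17.

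Among the lists of markers of other cell types, megakaryocyte and platelet markers fell in M1 cKO, 5 of 9 members (8 when adjusted over the list alone; camera adjusted p = 7.70e-06, and adjusted p = 0.143 with an estimated correlation). Among them were Itgb3, Vwf at -0.69 and the platelet chemokine gene Ppbp at -1.67. Fibroblast and stromal markers fell as a list (adjusted p = 0.0405, and adjusted p = 0.173 with an estimated correlation). Kdr, at -1.44, was the member that passed of 6. This call was lost when any of the 6 M1 libraries was left out (adjusted p between 0.0882 and 0.265). The remaining marker lists did not pass: neutrophil (adjusted p = 0.719, none of 8 members changed), T and NK cell (0.251, Cd4 at -0.91), erythroid (0.0741, and 0.0419 as lower without WT_M1 replicate 10, Car2 at -0.80), mast cell, basophil and eosinophil (0.433, Ccr3 at 0.76 and Kit at -1.68) and dendritic cell (0.504, Itgax at -0.95). Of the sex-linked genes only Xist was tested (-0.37 in M1, adjusted p = 0.0838). It had 6426 to 14679 counts in every library, and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had at most 5. The count of 2818 fell to 1658 without WT_M1 replicate 11 and to 1694 without cKO_M1 replicate 8. Of the called genes 48.2% were higher in cKO with TMM factors and 61.5% with library totals alone.

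**Figure D2:**
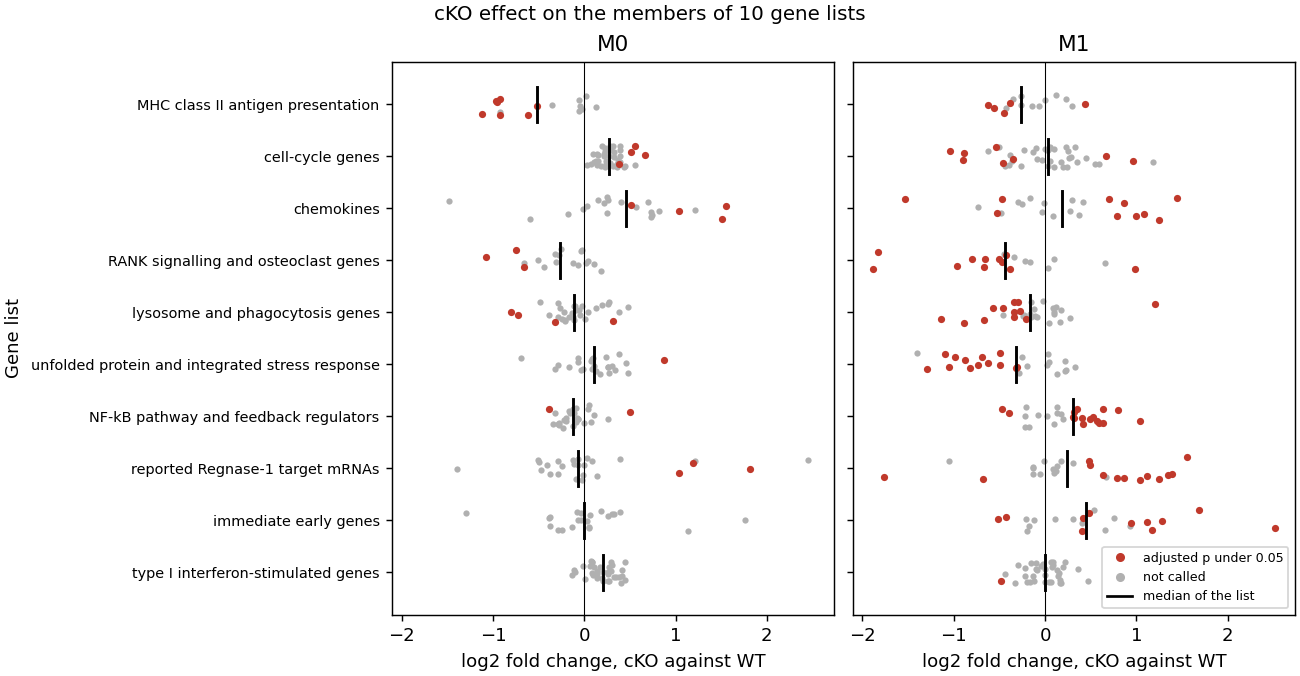
Log2 fold change of cKO against WT (axis linear in log2 units) for the measured members of 10 gene lists in M0 and in M1. Each point is a gene, red points passed the test over all genes and the bar marks the median; the MHC class II members lie lower in M0 and the RANK signalling, lysosome and stress response members lie lower in M1, while NF-kB pathway members lie higher in M1.

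The third comparison was the response to LPS and interferon-gamma itself, in WT and in cKO. In WT, Nos2, the inducible nitric oxide synthase, rose from 0.310 ± 0.135 to 5303 ± 417 CPM (SD, n = 3; log2 fold change 14.05, SE 0.36, adjusted p = 2.57e-14). In cKO it rose from 0.861 ± 0.600 to 7146 ± 737 CPM (log2 fold change 13.02, SE 0.33, adjusted p = 2.29e-14). The chemokine genes Cxcl9 and Ccl5, the acute-phase gene Saa3 and Ptgs2, which encodes cyclooxygenase-2, rose in WT by 13.57, 10.55, 11.96 and 11.53 and in cKO by 12.35, 10.81, 11.39 and 10.83 on the log2 scale. The cell-cycle gene Cdc20 fell from 86.8 ± 2.23 to 0.561 ± 0.0553 CPM in WT (log2 fold change -7.27, SE 0.12, adjusted p = 8.44e-16) and from 91.3 ± 0.652 to 0.643 ± 0.141 CPM in cKO (log2 fold change -7.14, SE 0.12, adjusted p = 7.81e-16). In WT 10787 of 15110 genes changed, 5175 higher and 5612 lower, and in cKO 10609, 5168 higher and 5441 lower.

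Il12b, Il23r and Ubd had 0 CPM in WT_M0 and 23.97, 15.5 and 14.1 CPM in WT_M1, so no fold change is given for them. Serpina3g, one of several near-identical Serpina3 genes whose counts are uncertain for that reason, rose from 0.125 to 330.0 CPM in WT. Among the largest falls, Aspm went from 72.7 ± 4.03 to 0.147 ± 0.0278 CPM and Rasgrp3 from 83.3 ± 8.84 to 0.219 ± 0.229 CPM in WT, and Plk1, a mitotic kinase gene, fell by 8.29 on the log2 scale. Of the other Regnase genes, Zc3h12a rose by 2.24 in WT and 2.38 in cKO, and Zc3h12d rose by 0.33 and 0.36, which turned to -0.25 and -0.18 with library totals alone.

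All 35 type I interferon-stimulated genes rose in both genotypes, Ifi205 by 5.94 in WT and 5.75 in cKO (camera adjusted p = 1.92e-12, and adjusted p = 0.266 with an estimated correlation in WT; adjusted p = 2.50e-11, and adjusted p = 0.272 with an estimated correlation in cKO). Of 30 interferon-gamma response genes, 29 rose in WT and 30 in cKO, Il18bp by 6.59 and 6.97 and Cd274 by 6.54 and 6.79 (camera adjusted p = 3.57e-42, and adjusted p = 0.0142 with an estimated correlation in WT; adjusted p = 7.54e-46, and adjusted p = 0.00924 with an estimated correlation in cKO). Proinflammatory mediators rose, 27 of 28 in WT and 27 in cKO, with Ptges at 7.81 and 7.47 (camera adjusted p = 3.77e-36, and adjusted p = 0.00303 with an estimated correlation in WT; adjusted p = 3.00e-38, and adjusted p = 0.00203 with an estimated correlation in cKO). The lists of chemokines (16 of 22 in WT and 16 in cKO), NF-kB pathway genes (21 of 27 in WT and 25 in cKO), reported Regnase-1 targets (20 of 26 in WT and 21 in cKO), NRF2 genes (15 of 19 in WT and 15 in cKO) and lysosome genes (23 of 31 in WT and 18 in cKO) also rose in both genotypes with the preset and the estimated correlation (highest estimated adjusted p = 0.0353 in WT and 0.0306 in cKO). Examples were Socs3 at 6.63 in WT and 7.30 in cKO, Hmox1 at 3.49 and 3.42 and Marco at 9.19 and 9.91. Of 42 cell-cycle genes, 40 fell in WT and 40 in cKO (camera adjusted p = 1.09e-63, and adjusted p = 0.00845 with an estimated correlation in WT; adjusted p = 4.67e-74, and adjusted p = 0.00277 with an estimated correlation in cKO). Of 24 cholesterol synthesis genes, 20 and 21 fell (camera adjusted p = 4.60e-08, and adjusted p = 0.0217 with an estimated correlation in WT; adjusted p = 5.82e-09, and adjusted p = 0.0146 with an estimated correlation in cKO). An example was Idi1 at -4.60 and -4.62.

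All 23 MHC class I genes rose in both genotypes, Tapbpl by 3.49 in WT and 3.51 in cKO (camera adjusted p = 4.72e-17, and adjusted p = 0.0604 with an estimated correlation in WT; adjusted p = 1.80e-17, and adjusted p = 0.0318 with an estimated correlation in cKO). Glycolysis and hypoxia genes rose, 23 and 24 of 27, Pfkfb3 by 5.33 and 5.23 (camera adjusted p = 8.49e-11, and adjusted p = 0.0718 with an estimated correlation in WT; adjusted p = 1.60e-11, and adjusted p = 0.0681 with an estimated correlation in cKO). Splicing factor genes fell, 50 and 54 of 81 against 13 and 8 higher, Hnrnph1 at -1.71 and -1.82 (camera adjusted p = 0.00970, and adjusted p = 0.444 with an estimated correlation in WT; adjusted p = 0.00717, and adjusted p = 0.436 with an estimated correlation in cKO). Alternative (M2) macrophage genes went both ways, 10 higher and 13 lower in WT, with Mrc1 at -5.48 and Il1rn at 6.94 (camera adjusted p = 0.605). Without TMM factors the median log2 fold change of all genes between M1 and M0 shifted to -0.65 in WT and -0.58 in cKO. Of the called genes 48.0% were higher in WT and 48.7% in cKO, against 23.5% and 24.2% with library totals alone, so directions are given relative to the TMM scale.

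The responses of WT and cKO shared 4448 genes higher in M1 in both genotypes, where independent lists of the same sizes would share 1770.0, and 4657 genes lower in both, against 2021 for independent lists. Of 29 lists tested, 18 passed in WT and 20 in cKO, and 9 and 10 of these with an estimated correlation. Across all genes the log2 fold changes of the 2 genotypes had a Pearson correlation of 0.930 and a Spearman correlation of 0.911, and genes are not independent replicates. The 2 comparisons used different libraries.

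The fourth comparison tested whether the effect of cKO differed between M1 and M0, as an interaction. Spp1 rose in cKO in M0 and fell in M1 (difference of the log2 fold changes -1.37, SE 0.12, adjusted p = 7.45e-05; n = 3 libraries per group in the edgeR model). Its levels were 791 ± 45.6 and 1133 ± 76.2 CPM in WT and cKO in M0 and 598 ± 41.8 and 332 ± 15.2 CPM in M1. The effect of cKO on Klf2 was higher in M1 than in M0 by 1.82 (SE 0.17, adjusted p = 0.000186). The effect on Il1b was higher by 2.95 (SE 0.53, adjusted p = 0.00485), the M0 level of Il1b being 0.328 ± 0.224 CPM in WT. The effect differed for 1233 of 15110 genes, 608 with a higher and 625 with a lower log2 fold change in M1 than in M0.

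Further genes with the smallest p were Cebpd at 1.65, Pou2f2 at 1.31, Rarg at 1.15 and Cited2 at 0.93, whose difference was positive. Those with a negative difference were Pcp4l1 at -1.56, Gadd45g at -1.53, Spdl1 at -1.50 and Fam198b at -1.32 (adjusted p of the 8 genes between 0.000480 and 0.000815). NF-kB pathway genes had 11 positive and 1 negative differences of 27 (13 and 2 when adjusted over the list alone; camera adjusted p = 2.94e-07, and adjusted p = 0.371 with an estimated correlation). Examples were Nfkbiz at 1.32, Nfkbie at 0.92 and Birc3 at 0.70. Unfolded protein and integrated stress response genes had 9 negative differences of 25 and none positive (13 when adjusted over the list alone; camera adjusted p = 3.06e-09, and adjusted p = 0.283 with an estimated correlation). Examples were Chac1 at -1.97 and Trib3 at -1.35. Cell-cycle genes had 10 negative and none positive of 42 (12 when adjusted over the list alone; camera adjusted p = 1.02e-05, and adjusted p = 0.410 with an estimated correlation). Examples were Kif23 at -1.03 and Ccne1 at -1.10. Immediate early genes had 5 positive and 1 negative of 22 (6 and 2 when adjusted over the list alone; camera adjusted p = 0.000482, and adjusted p = 0.410 with an estimated correlation). An example was Btg2 at 1.46. Extracellular matrix genes had 4 negative and 2 positive of 25 (9 and 4 when adjusted over the list alone; camera adjusted p = 0.0117, and adjusted p = 0.371 with an estimated correlation). Examples were Plau at -1.93 and Mmp14 at 1.39. Megakaryocyte markers had 2 negative of 9, Itgb3 and Gp1ba (camera adjusted p = 0.00483, and adjusted p = 0.410 with an estimated correlation). That call was lost without cKO_M0 replicate 1 (adjusted p = 0.105). The difference for Zc3h12c was -0.61 (SE 0.17, adjusted p = 0.0369). The call was lost in 9 of 20 alternatives with an adjusted p of up to 0.0999, each time without 1 library, while the difference stayed between -0.73 and -0.48. The count of 1233 became 640 without cKO_M0 replicate 3, 789 without WT_M0 replicate 4, 593 without WT_M0 replicate 6, 565 without cKO_M1 replicate 8 and 744 without WT_M1 replicate 11. It was 1884 with DESeq2 and 1972 with no low-count filter. The positive share was 49.3% with TMM factors and 60.5% with library totals alone.

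**Figure D3:**
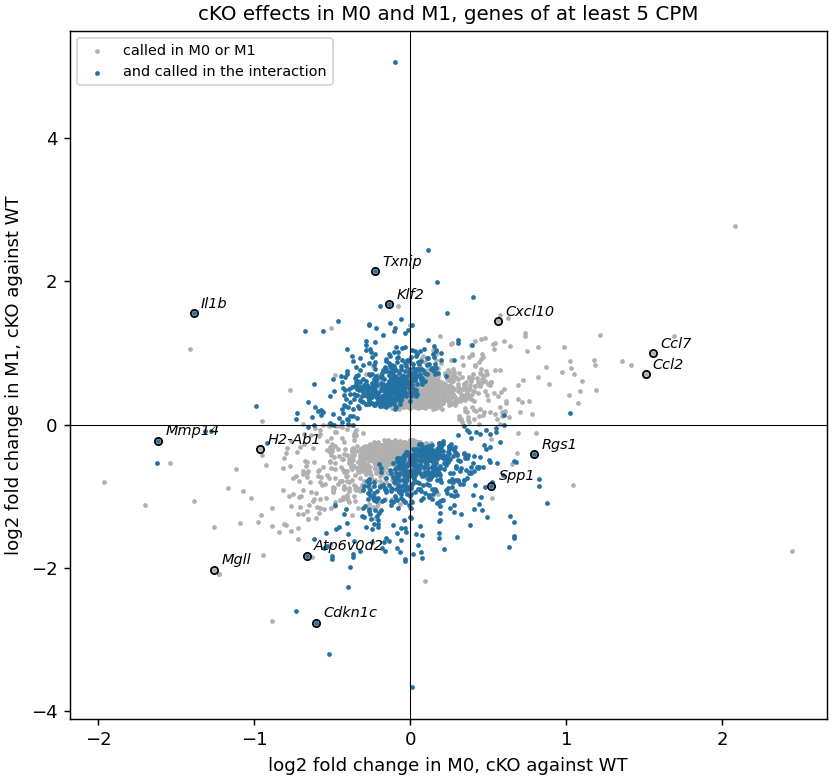
Log2 fold change of cKO against WT in M0 (horizontal axis) and in M1 (vertical axis), both in log2 units, for the 2591 genes with at least 5 CPM that were called in M0 or in M1. Each point is a gene, and the 1013 genes called in the interaction are coloured; Spp1 lies at 0.52 in M0 and -0.85 in M1.

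The fifth comparison took the mean of the cKO effects over M0 and M1, which a change in 1 of the states can carry. Axl fell by a mean of 0.72 on the log2 scale (SE 0.07, adjusted p = 0.000164; n = 3 libraries per group in the edgeR model), and was called in M1 but not in M0. Mfge8, which bridges apoptotic cells to phagocytes, fell from 258 ± 24.4 to 139.9 ± 27.0 CPM in M0 and from 242 ± 21.2 to 90.5 ± 23.7 CPM in M1 (mean log2 fold change -1.15, SE 0.11, adjusted p = 0.000164). Dio2, Mgll and Src fell, with -1.65, -1.64 and -0.66. So did Adra1a at -0.84, Aph1c at -0.80 and the IL-7 receptor gene Il7r at -0.79, and Marcksl1 rose by 0.72. Adra1a, Aph1c, Il7r and Marcksl1 were not called in both states when each state was tested alone. Ccl2, Ccl7 and Tnf rose by 1.11, 1.27 and 0.56. Over all genes 2262 changed, 1042 higher and 1220 lower.

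RANK signalling and osteoclast genes fell in the mean over both states, 9 of 18 against 1 higher (12 and 2 when adjusted over the list alone; camera adjusted p = 3.90e-08, and adjusted p = 0.0340 with an estimated correlation). Examples were Itgb3 at -1.19, Atp6v0d2 at -1.25 and Acp5 at -0.86. Acp5 was called in both states, whereas Itgb3 and Atp6v0d2 were called in M1 and not in M0. Lysosome and phagocytosis genes fell, 11 of 31 against 2 higher (13 and 2 when adjusted over the list alone; camera adjusted p = 3.68e-05, and adjusted p = 0.0238 with an estimated correlation). Examples were Gpnmb at -0.69 and Ctsz at -0.33. Megakaryocyte and platelet markers fell, 6 of 9 (camera adjusted p = 1.51e-06, and adjusted p = 0.132 with an estimated correlation). Glycolysis genes rose, 11 of 27 against 3 lower (camera adjusted p = 0.000235, and adjusted p = 0.335 with an estimated correlation). The RANK and lysosome lists were those that passed with an estimated correlation among the 15 lists that passed with the preset one. MHC class II genes fell, 8 of 15 (camera adjusted p = 1.02e-07, and adjusted p = 0.132 with an estimated correlation). Examples were Ciita at -0.87 and Cd74 at -0.59. B cell and plasma cell markers fell as a list in the same comparison, with 1 of 4 members past the test, Ighm (3 lower and 1 higher when adjusted over the list alone; camera adjusted p = 0.00118, and adjusted p = 0.132 with an estimated correlation). Their call was kept without any 1 library (adjusted p between 1.72e-12 and 0.00777). Chemokines rose, 7 of 22 against 1 lower (camera adjusted p = 0.00406, and adjusted p = 0.225 with an estimated correlation). The count of 2262 was 1308 without cKO_M0 replicate 3, 1263 without WT_M0 replicate 6 and 1427 without cKO_M1 replicate 8, and the higher share was 46.1% with TMM factors and 59.9% with library totals alone.

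Calls of the M0 and the M1 comparison overlapped among the genes lower in cKO: 54 genes were lower in both states, where independent lists would share 13.9 (Fisher's exact test, p = 1.84e-19), among them Mgll, Dio2, Sorbs3, Ciita, H2-Aa, Src, Acp5 and Itgax. Higher in both were 17 genes, against 8.98 for independent lists (Fisher's exact test, p = 0.0122), among them Ccl2, Ccl7, Cxcl2, Ptgs2 and Tnf. The 2 comparisons share no libraries, but they come from 1 fit with a shared estimate of the spread. The labels also do not state whether M0 and M1 cultures came from the same mice, so the 2 comparisons need not be independent. Fisher's exact test treats genes as independent, so its p does not measure the spread between libraries. Of the 90 genes called in both states, 71 had the same direction and 19 opposite directions. Higher in M0 and lower in M1 were 11, against 9.67 for independent lists (Fisher's exact test, p = 0.610). The reverse held for 8, against 12.9 (Fisher's exact test, p = 0.186). Neither number differed detectably from that of independent lists. Each of the 19 was called in the interaction, but this was nearly fixed by their selection, as the interaction is the difference between the same 2 effects. Across all genes the log2 fold changes in M0 and M1 had a Pearson correlation of 0.166, and genes are not independent replicates. Without 1 library the overlap of lower genes was 8 without cKO_M0 replicate 2, 1 without cKO_M0 replicate 3, 5 without WT_M0 replicate 4 and 3 without WT_M0 replicate 6. That of higher genes was 27 without cKO_M0 replicate 1, 28 without WT_M0 replicate 5, 3 without cKO_M0 replicate 2 and 0 without cKO_M0 replicate 3 or WT_M0 replicate 4 or 6.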

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

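The tests of the 3 patterns below were chosen only after the result was seen; the splits of the libraries were planned.

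The effect of cKO differed between M1 and M0 for 1233 genes by the interaction test, and 19 genes passed in opposite directions in the 2 states. Of the 19, 11 were higher in M0 and 8 lower, near the 9.67 and 12.9 that independent lists would share. Of the 1233, the named genes with at least 5 CPM and the smallest p were Spp1 (difference of the log2 fold changes -1.37), Klf2 (1.82), Spdl1 (-1.50), Pcp4l1 (-1.56), Rarg (1.15), Pou2f2 (1.31), Cited2 (0.93), Gadd45g (-1.53), Cebpd (1.65) and Fam198b (-1.32). Of 100 splits of the libraries within each state, drawn from 200, 1 gave as many genes, the real one, and the highest of the other splits gave 1122. This leaves chance open for the count of 1233, since such splits remove the effect of cKO itself and not only its difference between the states. Other splits that kept the real labels in M1 gave 361 to 1122 genes, and those that did not gave at most 1. Exchanging the genotypes in M0 alone, which was not among the splits drawn, turns the interaction into the mean over both states and would give 2262. For that mean 1 of 100 splits gave as many as the 2262 of the real split and the highest other gave 1648. Other splits that kept the real labels in M1 gave 361 to 1648 genes, and those that did not gave at most 2. The count of 2262 thus exceeded those of the other splits drawn. Chance differences between animals or cultures are not excluded by this, as the labels do not state that the replicates were separate. An effect present in M1 alone is not excluded either. The 6 libraries of a comparison of 2 groups can be split in 10 ways, which are too few for a share under 0.05. The real split, 1 of the 10, gave 244 genes in M0 against 51 in the highest other (cKO_M0 replicate 1 with WT_M0 replicates 4 and 6), 2818 against 0 in M1, 10787 against 0 for M1 against M0 in WT and 10609 against 0 in cKO. A split that mixes libraries of 2 real groups raises the fitted spread where the groups differ. The low counts of such splits, 0 included, were thus partly built in and do not measure what chance gives.

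Zc3h12c was lower in cKO in M1 and did not differ detectably in M0. Exchanged genotype labels of all M0 libraries are argued against by the genes called in both states, 71 with the same direction against 19 with opposite directions. A single wrong label in M0 was not decided by the bound set for it. Of 7 genes with at most 3 counts in each cKO_M1 library and at least 10 in each WT_M1 library, 4 averaged at least 10 counts in M0. Of these Ugt1a8 went with the label in all 6 M0 libraries, but 3 immunoglobulin genes (Igkc, Ighv1-26 and Iglv1) did not in cKO_M0 replicate 1. Ugt1a9 (0 counts in cKO_M0 against 12 to 19 in WT_M0) and Ugt1a6b (2 to 8 against 29 to 61), chosen after their values were seen, also went with the labels. Along the third principal component, chosen after its values were seen, cKO_M0 replicates 1, 2 and 3 lay at 10.02, 15.26 and 26.23. The WT_M0 libraries lay there at -23.94 to -13.62. Along the second, which held more of the variance, cKO_M0 replicate 1 at 2.13 lay nearer to the WT_M0 libraries, at 5.89 to 9.58. The Ugt1a genes and the third component thus argue against a wrong label. The immunoglobulin genes and the second component go with 1 in cKO_M0 replicate 1. That undeleted exons hold a constant share of the counts predicts no interaction, which was -0.61 (SE 0.17, adjusted p = 0.0369, 95% interval -0.97 to -0.25) and stayed between -0.73 and -0.48 in 20 alternatives, but it is left open because the bound asked for a call in each and 9 without 1 library had none, with an adjusted p of up to 0.0999. A difference in deletion between the states, a biological one that the design allows, was not tested, as the table holds no exon counts.

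Ugt1a8 and Ugt1a9, chosen after their values were seen, had 0 counts in all 6 cKO libraries, against 55 to 64 and 12 to 19 in WT_M0 and 12 to 24 and 7 to 8 in WT_M1: at least 19.6-fold lower for Ugt1a8 in M0 and at least 6.72-fold in M1, and at least 5.50-fold and 2.55-fold for Ugt1a9. The mouse genes of this cluster share exons, so reads may have been assigned to other members, and the sum over the cluster in cKO was 90.7% of WT in M0 and 59.9% in M1. Against this, no gain was seen in Ugt1a7c (3429 to 3795 counts in cKO_M0 against 3759 to 3895 in WT_M0, and 623 to 696 against 990 to 1075 in M1), Ugt1a6a (32 to 45 against 53 to 77 in M0) or Ugt1a6b (2 to 8 against 29 to 61 in M0), but it is left open, as the spread of Ugt1a7c in M0 exceeds what Ugt1a8 and Ugt1a9 lost. A segment from another strain around the Cre locus could also differ here: of the 78 tested genes between Ugt1a8 and Tnfrsf11a, both on chromosome 1, 16 passed over both states (20.5%, against 15.1% of the 14837 tested genes with a known position), at the 86.7th percentile of 13270 windows of as many genes. A bound first set at the 95th percentile would have counted this value against the segment, but was replaced by the median after the value was seen, since a segment need not change most of its genes, so the segment is left open, and a direct effect of the knockout was not tested.

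Immunoglobulin transcripts, chosen after their values were seen, were found in the 6 WT libraries and cKO_M0 replicate 1 (29 to 85 of 348 variable-segment genes with a count, Igkc at 31 to 386, Igha at 133 to 1430 and Jchain at 9 to 284 counts) and were near 0 in the other 5 cKO libraries (0 to 6 variable-segment genes, Igkc at 0 to 4, Igha at 0 to 6, Jchain at 0 to 8). Plasma cells carried through the culture may account for this, since at least 29 segments of both chain types and Jchain appeared in the same libraries; the segments are alike in sequence, so their counts are uncertain. WT RNA mixed into cKO_M0 replicate 1, or a wrong label there, would call for 62.0 counts of Ugt1a8 by the Igkc count and 0 were found. Ugt1a9 had 0 counts there against 12 to 19 in WT_M0, and Ugt1a6b had 2 against 29 to 61. These values argue against a mixture or a wrong label, but only for genes of 1 cluster that were chosen after their values were seen. An effect of the genotype on plasma cells was not tested.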

How the results depend on the processing

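All alternatives were chosen before the data were examined, except halved counts, which were chosen after seeing the data and kept every count of calls within 1.5 times (M0 360, M1 2813, interaction 1281, both states 2298). The cause of the changes was not tested. In M0 the count of 244 was 874 with DESeq2, 1182 with no low-count filter, 394 with only the groups compared, 491 with limma-voom and 33 with an added absolute log2 fold change of 1. With that threshold the counts were 520 in M1, 5842 and 5664 for M1 against M0 in WT and cKO, 300 in the interaction and 187 over both states; the interaction gave 1884 with DESeq2 and 1972 with no filter. The overlap of M0 and M1 calls, 17 higher and 54 lower, was 66 and 164 with DESeq2, 118 and 216 with no filter, and 0 and 9 with the added threshold; 26 were higher with library totals and 83 lower with only the groups compared. The overlap of the M1 responses, 4448 higher and 4657 lower, was 2292 and 7920 with library totals and 2127 and 2578 with the added threshold. With library totals 3 named values that were called in at least 1 of the 2 fits changed sign. They were Zc3h12d for M1 against M0 at -0.25 in WT and -0.18 in cKO, and Xist at -0.53 in WT. The interferon-gamma response list in M0 turned from lower to higher without cKO_M0 replicate 1 (adjusted p = 0.00780, against up to 0.920 without WT_M0 replicate 4).

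Leaving out 1 library gave 1 (without cKO_M0 replicate 3) to 407 genes (without WT_M0 replicate 5) in M0, with 32 without cKO_M0 replicate 2, 12 without WT_M0 replicate 4 and 4 without WT_M0 replicate 6. It gave 1658 (without WT_M1 replicate 11) to 3082 in M1, with 1694 without cKO_M1 replicate 8. It gave 10319 to 10454 and 9998 to 10423 for M1 against M0 in WT and cKO. The interaction gave 565 (without cKO_M1 replicate 8) to 1576, with 640, 789, 593 and 744 without cKO_M0 replicate 3, WT_M0 replicates 4 and 6 and WT_M1 replicate 11. Over both states it gave 1263 (without WT_M0 replicate 6) to 2928, with 1308 and 1427 without cKO_M0 replicate 3 and cKO_M1 replicate 8. The overlaps were 0 to 28 higher and 1 to 79 lower for M0 and M1, and 4279 to 4443 and 4432 to 4564 for the M1 responses. Zc3h12c lay between -0.20 and 0.03 in M0 and between -0.81 and -0.62 in M1, where the adjusted p was 0.000211 to 0.00761. Over the 623 values of named genes, a value counted as kept if neither fit called it, whatever its sign. It also counted as kept if both fits called it in the same direction. By this rule the alternatives kept the value 9709 times and lost the call 399 times (352 of these by leaving out a library). They gained the call 70 times, and 3 times turned the sign of a value called in at least 1 of the 2 fits. These totals pool all contrasts, M1 against M0 included, and values that neither fit called. They therefore do not describe the M0 calls, of which 1 gene was left without cKO_M0 replicate 3. No list passed with an estimated correlation in M0, M1 or the interaction (0 of 11, 14 and 6 that passed with the preset one), against 9 of 18 and 10 of 20 for M1 against M0 in WT and cKO and 2 of 15 over both states. With fry, MHC class II (adjusted p = 0.00974), RANK (0.0141), cell-cycle (0.0173), lysosome (0.00618) and chemokine genes (0.0244) passed in M0. The other preset calls in M0 were lost with fry (0.227 to 0.538). Those in M1 were kept, except interferon-gamma response (0.132) and MHC class II genes (0.0597). In the interaction, the calls of cell-cycle genes and megakaryocyte markers were lost with fry (0.0783 each). No paired analysis was possible because the replicate numbers, 1 to 12, are shared by no libraries. The labels do not state whether M0 and M1 cultures came from the same mice, so a pairing is not excluded. In the simulated data 68.7% of 1.5-fold changes were found in M0 and 76.1% in M1. Genes varied independently there and 200 were changed, so these shares need not hold for the real libraries.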

Other observations

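Genes that passed in opposite directions in the 2 states, chosen after their values were seen, included the G1/S cyclin gene Ccne1 (log2 fold change of cKO against WT 0.56 in M0 and -0.54 in M1). They also included the polyamine synthesis gene Odc1 (0.68 and -0.52), the regulators of G protein signalling Rgs1 (0.79 and -0.42) and Rgs2 (0.44 and -0.45) and the phosphatase gene Dusp5 (0.82 and -0.86). The reverse held for Nod1 (-0.42 and 0.25), Mefv (-0.43 and 0.41), Birc3 (-0.39 and 0.31), Vsir (-0.33 and 0.23), Arrdc2 (-0.51 and 0.40), Ahrr (-0.33 and 0.26), Galc (-0.42 and 0.48) and Rarg (-0.41 and 0.74). None of these genes passed in M0 without cKO_M0 replicate 3, where 0 genes were higher and the 1 lower gene was also lower in M1. Genes with opposite directions were 11 and 8, against 9.67 and 12.9 for independent lists. Genes lower in both states, also chosen after their values were seen, included Lox, which encodes a collagen cross-linking enzyme (-1.63 and -0.54), and Fstl1 (-1.38 and -2.15).

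Most markers of other cells were at low levels: the median over a list's members of the mean level in the 4 groups was 0.0788 CPM for the neutrophil list, 0.119 CPM for the stromal, 0.762 CPM for the dendritic cell, 1.01 CPM for the megakaryocyte, 0.0285 CPM for the B cell, 0.0162 CPM for the mast cell, basophil and eosinophil, 0.0144 CPM for the T and NK cell and 0.0184 CPM for the erythroid list. From 0 to 4 members of a list reached 10 CPM in a group. The highest group means were 289 CPM for the neutrophil list (Csf3r), 322 CPM for the stromal list (Kdr) and 814 CPM for the dendritic cell list (Bst2). They were 105 CPM for the megakaryocyte list (Pf4), 53.1 CPM for the B cell list (Ighm), 24.7 CPM for the mast cell, basophil and eosinophil list (Ccr3), 16.5 CPM for the T and NK cell list (Cd4) and 9.19 CPM for the erythroid list (Car2). Several of these genes are also expressed by macrophages. Mitochondrial transcripts made up 1.48% ± 0.114 (SD, n = 3) of counts in WT_M0, 1.71% ± 0.161 in cKO_M0, 0.995% ± 0.133 in WT_M1 and 0.950% ± 0.0441 in cKO_M1. The mean chi-square per degree of freedom between replicate pairs was 7.12 to 34.5 on halved counts, where counting noise alone gives 1.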
